A study of Mus musculus with 20 samples.

How the data were processed

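Total RNA from mouse embryonic fibroblasts was measured on Agilent two-colour arrays, with 1 sample per channel. Per the labels, each of the 20 samples pooled RNA from 4 plates, was amplified and carried Cy3 or Cy5, and the 4 samples of a group were independent. Nothing further says how the cultures were started, so the p-values measure the spread between these samples. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction (10.7.3.1 for slide 1, 11.0.1.1 for slide 2), so slide, scan and software version cannot be told apart. The deposited intensity values are the median pixel brightness of each spot and of its local background, not normalized, with marks for spots well above background, saturated or outlying. Each array's file was deposited for both of its samples, and all 20 copies equalled their partner's. The authors' deposited series matrix holds log2 intensity per spot. Its columns have medians of 6.90 to 6.91 and nearly equal distributions. Each correlated with log2 of its own channel at 0.999 to 1.000, so that its scale is settled and it is not centred by gene. The submitters' processing notes name R 2.15 and limma. Their steps are not given in the sources used here.

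Signals were corrected with normexp (offset 50), normalized by loess within arrays with control and outlying spots at weight 0, and then scaled between arrays by quantiles of the average intensity (Aquantile), in R 4.3.3 with limma 3.58.1. The plan named mean signals, which were not used here: the median signal took their place. Control spots (3671 of 62976) were then dropped and outlying spots left out, which left 59305 spots of 55681 probes. The spots of a probe were averaged. Of 28116 probes with a RefSeq transcript accession, 26582 were named through a table of RefSeq genes of the assembly GRCm38.p6, which gave 20145 symbols and matched 20869 of 22232 accessions. The other 29099 probes stayed unnamed and were tested as transcripts of their own. The array's annotation is on another build, mm9 per the file headers, so no coordinates are given. A probe was kept if well above background in at least 4 of 20 samples, and the brightest probe stood for its gene. This gave 24250 tested genes and transcripts, 14242 of them named. Quantile and loess steps assume that most genes do not change, so that a change common to all genes would not be seen.

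Each gene was fitted with limma over all 20 samples with terms for group, dye and slide, and with the array as a random block (correlation 0.249). Moderated tests (eBayes; 13 residual and 4.56 prior degrees of freedom) were two-sided, adjusted by Benjamini-Hochberg over all genes tested, and called at an adjusted p under 0.05. Dye and slide terms were past that threshold for 6403 and 10491 genes, with median sizes of 0.15 and 0.31 among those. The comparisons were each time against the control, each time against the time before, and the interaction of slide with the 6 h change. Other probes of called genes went in the same direction in 83.4% to 88.7% of cases. Of the genes named by rule, only Mrps25 had a probe called in the opposite direction. For a gene not well above background in any sample of a group, the fold is a lower bound: the brighter group's mean over, per sample of the dimmer group, the higher of its own value and the lowest signal among probes well above background, taken with and without the dye and slide terms removed, whichever gave the smaller fold.

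Before the data were examined, 32 gene lists were fixed from general knowledge of mitochondrial stress and fibroblasts, with markers of other cell types. The 13 mitochondrially encoded mRNAs had no matched probe and were not analysed here. Lists were tested with camera on values whitened by the array correlation, with a preset correlation of 0.01 between genes and again with an estimated one, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, and fry asks whether its genes move on balance in 1 direction. Over the 4 times against control, 66 of 124 list tests were past the threshold with the preset correlation and 12 with an estimated one. These 12 were the integrated stress response and mitochondrial aminoacyl-tRNA synthetases at 6 h, G2/M and inflammatory genes at 24, 48 and 72 h, cholesterol synthesis at 24 and 48 h, cytosolic ribosomal proteins at 48 h and G1/S at 72 h. Fry called 102. Among lists past the threshold, the median changed sign under another scaling only for glycolysis and hypoxia-inducible genes between 48 h and 72 h, and no scaling moved the median of all genes by over 0.1.

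Genes were named by a rule fixed in advance. It took the 8 largest rises and 8 largest falls per time with a symbol, a call and signal in both groups. Their 4 treated and 4 control values also had to show no overlap once the fitted dye and slide terms were removed. The rule added up to 3 bounded genes per direction, up to 4 members per list by smallest adjusted p and 17 genes fixed by name. It also took the 3 largest changes per direction between successive times. Simulated data with known changes, drawn from the fitted values, gave these recoveries of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale: 44%, 98%, 100% and 100% at 6 h, and 22%, 88%, 98% and 100% at 24 h. They were 44%, 94%, 100% and 100% at 48 h, and 14%, 92%, 98% and 98% at 72 h, over 24205 genes. Far fewer genes changed in these simulations than were called in the data, which makes the adjusted threshold stricter there. False calls were 3.9%, 7.2%, 8.6% and 6.8% of calls. Of 124 list tests without effects, 0 were called. Errors were drawn independently for each gene there, so this does not test how correlation between genes affects the list tests.

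Alternatives covered background correction, scaling, the processed signals, the authors' series matrix, filters on dim probes, slide, dye and array terms, the samples in the fit, the probe chosen per gene, thresholds and each sample left out. A fit without array 10 and one over named genes only were added after seeing the data. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.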

Results

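The data were expression profiles of mouse embryonic fibroblasts, connective tissue cells cultured from embryos, of a Balb/c background, grown in medium with added uridine, which lets cells divide when their respiratory chain fails. The cells received actinonin at 150 µM for 6, 24, 48 or 72 h, or the ethanol carrier at 3 µl/ml. Actinonin is a hydroxamate antibiotic that inhibits peptide deformylase, the enzyme that removes the formyl group from newly made proteins in bacteria and mitochondria. The comparisons ask how the cells' transcripts changed over the exposure. Each of the 5 groups held 4 independent samples, each pooled from 4 plates, and 2 samples of each group carried the dye Cy3 and 2 carried Cy5. The 20 samples were hybridised in pairs on 10 arrays of 62976 spots, with 2 arrays on slide 1 and 8 on slide 2. Slide 1 held 2 controls and 2 samples of 6 h, and all samples of 24, 48 and 72 h lay on slide 2. The later times thus shared a slide with only 2 of the 4 controls. The other 2 enter those comparisons through the fitted slide term, which rests on the controls and 6 h samples. The share of spots well above background was 50.8% to 58.7% per sample on 9 arrays. It was 66.4% and 70.5% for the pair on array 10, a control and a 48 h sample. Median signals per channel were 85 to 173, and 1 spot of 1 sample was saturated. The number of arrays limits the precision. The carrier control has a time of 0 h in the labels, which do not say whether it was harvested at the start or after a time in culture. An effect of time in culture can therefore not be separated from that of actinonin.

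After 6 h of actinonin the largest rise of a named gene was that of Gadd45a, which encodes a growth arrest protein. It was 5.63-fold higher than in the carrier control, a log2 change of 2.49 ± 0.08 (± standard error here and throughout, n = 4 per group; adjusted p = 8.07e-13). The pseudokinase gene Trib3 rose by 2.41 ± 0.12, the transcription factor gene Atf3 by 2.02 ± 0.08 and Arid5a by 1.83 ± 0.07. Next came the glutathione-degrading enzyme gene Chac1 at 1.80 ± 0.07, the hormone gene Fgf21 at 1.77 ± 0.13, the kinesin gene Kif21b at 1.77 ± 0.08 and Ppp1r15a, a regulatory subunit of the phosphatase that acts on eIF2 alpha, at 1.73 ± 0.08. Of the genes tested as targets of the integrated stress response, the programme driven by ATF4 and CHOP, 36 of 36 rose (36 adjusted over the list alone), with a median log2 change of 1.03. Ddit3, which encodes CHOP, rose by 1.68 ± 0.08, the serine synthesis gene Psph by 1.42 ± 0.08, the asparagine synthetase gene Asns by 1.01 ± 0.08 and Atf4 itself by 1.05 ± 0.09. This list was past the threshold against all other genes (adjusted p = 5.59e-46 with the preset correlation, adjusted p = 0.0404 with an estimated correlation).

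Other lists had more genes called up than down at 6 h, though cytosolic ribosomal protein genes hardly moved. Of these lists, only mitochondrial aminoacyl-tRNA synthetases were past the threshold with an estimated correlation. Of 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 16 rose and 0 fell (17 and 1 adjusted over the list alone), Gars by 0.80 ± 0.07 and Wars by 0.76 ± 0.07. The list's call was lost with adjusted p = 0.0623 with an estimated correlation. Of 32 ribosome biogenesis genes 25 rose and 1 fell (28 and 1 adjusted over the list alone), Nop14 by 0.64 ± 0.06 and Wdr43 by 0.58 ± 0.06 (adjusted p = 0.134 with an estimated correlation). Of 22 serine and one-carbon genes 11 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation). In this list, 6 genes are also in the stress response list. Of 78 cytosolic ribosomal protein genes 2 rose and 0 fell (0 and 0 adjusted over the list alone; median 0.039; adjusted p = 0.621 with an estimated correlation). Mitochondrial gene expression factors rose in 18 of 41 and fell in 0 (19 and 1 adjusted over the list alone; median 0.15; adjusted p = 0.0623 with an estimated correlation), and mitochondrial aminoacyl-tRNA synthetases rose in 8 of 20 and fell in 0 (9 and 0 adjusted over the list alone; median 0.11; adjusted p = 0.0404 with an estimated correlation). Pdf, the gene of the mitochondrial peptide deformylase, rose by 0.20 ± 0.05 (adjusted p = 0.00878). Tfam, which packages mitochondrial DNA, rose by 0.22 ± 0.05. Among 24 mitochondrial chaperones and proteases 8 rose and 2 fell (10 and 2 adjusted over the list alone), led by the chaperone gene Dnaja3 at 0.84 ± 0.06 and the matrix protease gene Lonp1 at 0.76 ± 0.06, with Hspd1 at 0.25 ± 0.06. The list's adjusted p was 0.0623 with an estimated correlation.

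The genes that fell most at 6 h were the secreted proteases Adamts1 (-1.17 ± 0.12) and Adamts5 (-1.02 ± 0.11), the heat-inducible chaperone Hspa1a (-1.02 ± 0.09), Hexim1 (-0.98 ± 0.05), an inhibitor of transcription elongation, Gas1 (-0.95 ± 0.10), Crip1 (-0.86 ± 0.06), the peptide hormone Adm (-0.83 ± 0.07) and Txnip (-0.82 ± 0.10). Cholesterol synthesis genes, targets of SREBP2, fell in 23 of 25 and rose in 0 (24 and 0 adjusted over the list alone), with a median of -0.40, Hmgcs1 at -0.65 ± 0.15 and Lss at -0.27 ± 0.06; adjusted p = 0.0623 with an estimated correlation. Genes of G2/M and mitosis fell in 18 of 30 and rose in 0 (20 and 0 adjusted over the list alone), with a small median of -0.17 and adjusted p = 0.0623 with an estimated correlation. G1/S and DNA replication genes fell in 15 of 37 and rose in 3 (20 and 3 adjusted over the list alone; adjusted p = 0.0694 with an estimated correlation), Cdc6 at -0.65 ± 0.05. Endoplasmic reticulum unfolded protein response genes fell in 15 of 24 and rose in 3 (16 and 4 adjusted over the list alone); the chaperone cofactor Sdf2l1 was at -0.78 ± 0.06. Herpud1, which serves protein degradation at that membrane, rose by 0.93 ± 0.07 (the list at adjusted p = 0.284 with an estimated correlation). Respiratory chain genes of complexes II to V fell in 15 of 41 and rose in 2 (18 and 2 adjusted over the list alone), Uqcrh at -0.67 ± 0.07 (adjusted p = 0.284 with an estimated correlation).

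At 6 h, 6002 of 24250 tested transcripts and genes were past the threshold, 3280 up and 2722 down, with a median size of 0.26 on the log2 scale among those called. Of these, 68 rose and 4 fell by at least 2-fold. The controls and the 6 h samples each lay on both slides. On slide 1 they shared arrays with each other, and on slide 2 only with samples of 48 h. A difference between the slides can therefore not be told apart from one of array pairing. Within slide 1, with 2 samples per group, 1.1e2 genes (rounded) were called, and within slide 2, 4697. The list medians on slide 1 and slide 2 were 0.87 and 1.22 for the integrated stress response, 0.35 and 0.52 for cytosolic aminoacyl-tRNA synthetases, 0.28 and 0.35 for ribosome biogenesis, -0.26 and -0.56 for cholesterol synthesis and -0.18 and -0.18 for G2/M. None of the 17 lists past the threshold at 6 h in the fit over both slides, which favours agreement, changed sign on either slide. With only the 8 samples of the 2 groups in the fit, 2782 genes were called.

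After 24 h other genes showed the largest changes. Cdsn, which encodes corneodesmosin, an adhesion protein of cornified epidermis, was 23.9-fold higher than in the control (log2 4.58 ± 0.11, n = 4 per group; adjusted p = 1.27e-14), after 2.30-fold at 6 h, and the secreted carbonic anhydrase gene Car6 was 21.5-fold higher (4.43 ± 0.16). Cox6a2, the muscle-type isoform of a cytochrome c oxidase subunit, rose by 2.81 ± 0.14, the endopeptidase gene Ecel1 by 2.68 ± 0.11, Angptl6 by 2.61 ± 0.10 and Gadd45a by 2.59 ± 0.09. The glutathione transferase gene Gsta2, whose probe can also take up close copies such as Gsta1, rose by 2.56 ± 0.09, and the aldo-keto reductase gene Akr1b7 by 2.54 ± 0.13. Ecel1 and Akr1b7 were well above background in only 3 of 4 controls. Among the steepest falls, the peptide hormone gene Cck was at -3.53 ± 0.10, the chemokine gene Ccl9 at -2.26 ± 0.10, Vip at -2.21 ± 0.11, the hyaluronan synthase gene Has2 at -2.14 ± 0.13, the matrix protein gene Fmod at -2.0 ± 0.13, the extracellular superoxide dismutase gene Sod3 at -1.76 ± 0.11, Igf1 at -1.73 ± 0.08 and the cornified envelope gene Lce1g, which has close paralogs, at -1.71 ± 0.14.

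The cell cycle list with the largest change at 24 h was that of mitosis. All 30 tested G2/M genes fell (30 adjusted over the list alone), with a median of -1.04, the mitotic kinase gene Plk1 at -1.36 ± 0.06, Cdc20 at -1.27 ± 0.06, Kif23 at -1.21 ± 0.05 and the cyclin gene Ccnb1 at -1.02 ± 0.07 (adjusted p = 4.69e-31, and adjusted p = 0.00335 with an estimated correlation). G1/S and DNA replication genes fell in 16 of 37 and rose in 3 (16 and 3 adjusted over the list alone; median -0.099; adjusted p = 0.179 with an estimated correlation), and the median came as close to 0 as -0.057 over 7 other scalings, with the preset call lost under 2. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was at -0.15 ± 0.09, not past the threshold. All 25 cholesterol synthesis genes fell (25 adjusted over the list alone; median -0.91), Lss at -1.20 ± 0.07, Pmvk at -1.16 ± 0.07 and Fdps at -1.14 ± 0.06 (adjusted p = 0.0365 with an estimated correlation). Inflammatory cytokine and NF-kB target genes fell in 16 of 19 and rose in 0 (16 and 0 adjusted over the list alone; median -0.64; adjusted p = 0.0365 with an estimated correlation), including the chemokine genes Ccl7 (-1.68 ± 0.11), Ccl2 (-1.67 ± 0.10) and Cxcl1 (-1.11 ± 0.10). Macrophage and leukocyte markers fell in 3 of 6 and rose in 0 (3 and 0 adjusted over the list alone; median -0.27; adjusted p = 0.128 with an estimated correlation), Cd14 at -0.72 ± 0.08, so a loss of such cells is not separated from a change within fibroblasts. Extracellular matrix and contractile genes fell in 23 of 30 and rose in 1 (24 and 1 adjusted over the list alone; median -0.43; adjusted p = 0.128 with an estimated correlation), Thbs1 at -1.09 ± 0.10, Col1a1 at -0.86 ± 0.09 and the smooth muscle actin gene Acta2 at -0.33 ± 0.06. Endoplasmic reticulum chaperone and response genes fell in 15 of 24 and rose in 4 (15 and 4 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation), Hsp90b1 at -0.99 ± 0.08 and Creld2 at -0.89 ± 0.06.

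Several lists were higher at 24 h. The integrated stress response genes rose in 33 of 36 and fell in 0 (33 and 0 adjusted over the list alone), with a median of 0.71 (adjusted p = 2.77e-19; adjusted p = 0.116 with an estimated correlation), Ddit3 by 1.89 ± 0.10 and Slc7a11, the cystine transporter gene, by 1.23 ± 0.10. Cytosolic ribosomal protein genes rose in 58 of 78 and fell in 0 (62 and 0 adjusted over the list alone), each by little: the median was 0.23, with Rpl12 at 0.45 ± 0.07 (adjusted p = 0.0834 with an estimated correlation). Lysosome and autophagy genes rose in 19 of 30 and fell in 1 (19 and 2 adjusted over the list alone; median 0.34; adjusted p = 0.0940 with an estimated correlation), the sialidase gene Neu1 by 1.07 ± 0.07 and the cathepsin gene Ctsl by 1.03 ± 0.07. Genes measured above background in the 24 h samples and not in the controls gave lower bounds: Try5 was at least 3.28-fold, its paralog Try4 at least 2.30-fold and Nrip2 at least 2.26-fold higher. In the other direction Lce1h was at least 1.73-fold, the metalloproteinase gene Mmp3 at least 1.59-fold and the keratin gene Krt7 at least 1.55-fold lower than in the controls, where 3 of 4 samples measured Krt7. In all, 9771 genes were called, 5091 up and 4680 down, with 167 up and 194 down by at least 2-fold. With loess within arrays but no scaling between arrays the count was 6134; within slide 2 it was 10264.

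At 48 h the largest rises were those of Cdsn (4.66 ± 0.10, adjusted p = 1.27e-15), Car6 (4.35 ± 0.14), Gadd45a (3.13 ± 0.08), Cox6a2 (2.83 ± 0.12), Angptl6 (2.81 ± 0.08), the adhesion receptor gene Cxadr (2.73 ± 0.08), Kif21b (2.40 ± 0.09) and Gdap1l1 (2.38 ± 0.08). Cck (-3.51 ± 0.09), Vip (-2.21 ± 0.10), the Wnt antagonist gene Sfrp2 (-2.16 ± 0.11), Fmod (-2.12 ± 0.11), Ccl9 (-2.11 ± 0.09), Has2 (-2.07 ± 0.12), the choline transporter gene Slc5a7 (-2.04 ± 0.08) and Lce1g (-1.94 ± 0.12) fell most. Cholesterol synthesis genes fell in 25 of 25 (25 adjusted over the list alone), with a median of -1.25 and Hmgcs1 at -1.40 ± 0.16 (adjusted p = 0.0226 with an estimated correlation). G2/M genes fell in 30 of 30 (30 adjusted over the list alone), with a median of -0.67, Ccnb1 at -0.67 ± 0.06 and the survivin gene Birc5 at -0.95 ± 0.05 (adjusted p = 0.0148 with an estimated correlation). Cytosolic ribosomal protein genes rose in 66 of 78 and fell in 0 (68 and 0 adjusted over the list alone; median 0.33; adjusted p = 0.0226 with an estimated correlation), Rpl12 by 0.67 ± 0.06 and Rps27 by 0.64 ± 0.06. Integrated stress response genes rose in 35 of 36 (36 adjusted over the list alone), with a median of 0.88 (adjusted p = 0.0625 with an estimated correlation). Inflammatory genes fell in 15 of 19 and rose in 0 (15 and 0 adjusted over the list alone; adjusted p = 0.0338 with an estimated correlation). Macrophage and leukocyte markers were at -0.28 on average (median -0.14), so a loss of such cells is not separated from a change within fibroblasts here either. Extracellular matrix genes fell in 20 of 30 and rose in 2 (20 and 2 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), Col1a1 at -1.46 ± 0.08.

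Bounds at 48 h were smaller than the leading changes. Try5 was at least 1.81-fold, the fucosyltransferase gene Fut1 at least 1.65-fold and Nrip2 at least 1.63-fold higher than in the controls, where no sample had them well above background. Agtr2, an angiotensin receptor gene, was at least 1.87-fold, Mmp3 at least 1.69-fold and Cd300lb at least 1.60-fold lower. Respiratory chain genes of complexes II to V fell in 23 of 41 and rose in 3 (25 and 4 adjusted over the list alone), with Uqcrh at -0.73 ± 0.07, Atp5k at -0.42 ± 0.05 and, in the other direction, Cox7a2l at 0.60 ± 0.05 (median -0.17; adjusted p = 0.245 with an estimated correlation). Over 7 other scalings this median came as close to 0 as -0.093, and the call with the preset correlation was lost under 1. The 48 h count was 10139, with 5200 up and 4939 down and 174 up and 215 down by at least 2-fold. Without array 10, which held 1 control and 1 sample of 48 h, 8336 genes were called, and within slide 2, 10667.

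The 72 h comparison had the highest count of the 4 against the control, with 11605 genes called, 6076 up and 5529 down, and 363 up and 348 down by at least 2-fold. Cdsn was 40.9-fold higher (5.35 ± 0.11; adjusted p = 4.16e-16), Car6 rose by 4.85 ± 0.16, the teneurin gene Tenm4 by 3.58 ± 0.10, the glycosyltransferase gene B4galnt2, measured in 3 of 4 controls, by 3.31 ± 0.09, Cxadr by 3.26 ± 0.09, Gadd45a by 3.21 ± 0.09, Cox6a2 by 3.19 ± 0.14 and Angptl6 by 3.01 ± 0.10. Cck was 35.5-fold lower (-5.15 ± 0.10; adjusted p = 4.16e-16). Lce1g (-2.99 ± 0.14), Vip (-2.74 ± 0.11), Has2 (-2.72 ± 0.13), the guanine nucleotide exchange factor gene Rasgrf1 (-2.68 ± 0.10), Lce1i (-2.55 ± 0.15), the interleukin-33 receptor gene Il1rl1 (-2.54 ± 0.14) and Ccl7 (-2.49 ± 0.11) followed. By bound, Try5 was at least 4.02-fold, Nrip2 at least 3.03-fold and Try4 at least 2.80-fold higher, and the mast cell protease gene Mcpt8 was at least 2.79-fold, the granzyme gene Gzme at least 2.57-fold and Sh2d1b1 at least 2.28-fold lower.

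Both cell cycle lists were lower at 72 h. G2/M genes fell in 30 of 30 (30 adjusted over the list alone; median -1.01; adjusted p = 0.0101 with an estimated correlation), Plk1 at -1.33 ± 0.06 and Birc5 at -1.35 ± 0.05. G1/S and DNA replication genes fell in 27 of 37 and rose in 1 (27 and 3 adjusted over the list alone; median -0.25; adjusted p = 0.0485 with an estimated correlation), the ribonucleotide reductase genes Rrm2 at -1.09 ± 0.07 and Rrm1 at -0.81 ± 0.05, Tk1 at -0.99 ± 0.05 and Mcm5 at -0.59 ± 0.07. Cdkn1a fell by 0.50 ± 0.09. Cholesterol synthesis genes fell in 24 of 25 and rose in 0 (24 and 0 adjusted over the list alone; median -1.0; adjusted p = 0.0530 with an estimated correlation). Inflammatory genes fell in 16 of 19 and rose in 0 (16 and 0 adjusted over the list alone; median -0.69; adjusted p = 0.0485 with an estimated correlation). Macrophage and leukocyte markers were at -0.30 on average (median -0.14), with the same limit as at 24 h. Integrated stress response genes rose in 32 of 36 and fell in 0 (32 and 0 adjusted over the list alone; median 0.84; adjusted p = 0.142 with an estimated correlation). Cytosolic ribosomal protein genes rose in 56 of 78 and fell in 2 (59 and 2 adjusted over the list alone; median 0.23; adjusted p = 0.126 with an estimated correlation). Lysosome and autophagy genes rose in 20 of 30 and fell in 3 (21 and 3 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), Ctsl by 1.23 ± 0.07 and Hexa by 1.03 ± 0.08. Within slide 2, 11859 genes were called. At 24, 48 and 72 h, no list past the threshold changed sign within slide 2 and the medians there differed from those given by at most 0.10, 0.12 and 0.09. Slide 2 held all samples of these times, and the lists were those past the threshold in the fit that includes them. Agreement was therefore favoured beforehand, and only the slide 1 controls and 6 h samples were left out.

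Followed over the 4 times, the named genes took different courses. Lonp1 was at 0.76 ± 0.06, 1.14 ± 0.07, 1.32 ± 0.06 and 1.42 ± 0.07 at 6, 24, 48 and 72 h, and the chaperone gene Hspa9 at 0.54 ± 0.06, 0.85 ± 0.07, 0.87 ± 0.06 and 1.05 ± 0.07. Hspd1 stayed small, at 0.25 ± 0.06, 0.26 ± 0.07, 0.23 ± 0.06 and 0.23 ± 0.07. Gdf15, a secreted stress-induced factor, was at 1.27 ± 0.08, 0.36 ± 0.10, 0.74 ± 0.09 and -0.11 ± 0.10, the last not past the threshold. Fgf21 was at 1.77 ± 0.13, 1.27 ± 0.16, 1.52 ± 0.14 and 1.08 ± 0.16. Ccl7 and Ccl2 rose at 6 h (0.47 ± 0.09 and 0.48 ± 0.08) and fell at 24 h. Pdf was at -0.01 ± 0.06, 0.13 ± 0.06 and -0.13 ± 0.06 from 24 h and Tfam at 0.15 ± 0.06, 0.07 ± 0.05 and 0.03 ± 0.06, none past the threshold. Over all genes tested, 1594 rose and 1353 fell at all 4 times. Another 8931 were called at none, and 821 rose at one time and fell at another. Genes with rises only at 6 h numbered 947, by calls, which do not test the difference between times.

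**Figure D1:**
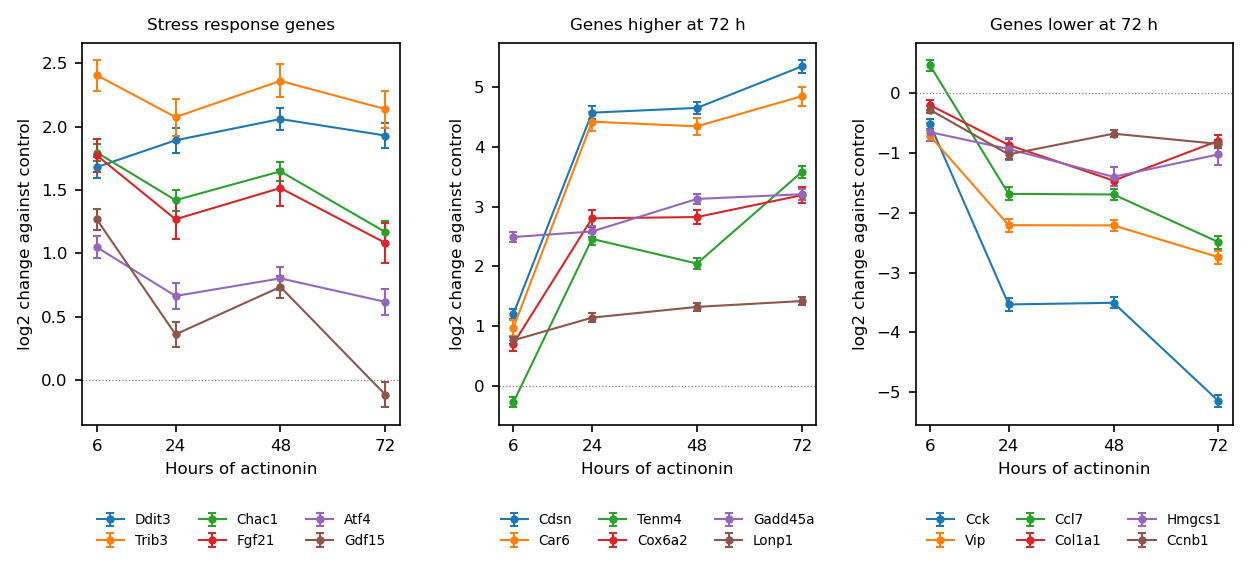
Log2 change against the control (y axis) of 18 named genes after 6, 24, 48 and 72 h of actinonin (x axis, hours), in panels of stress response genes, genes higher at 72 h and genes lower at 72 h; points are estimates from 4 samples per group and bars are ± standard error. Cdsn stands at 5.35 and Cck at -5.15 at 72 h, and Gdf15 goes from 1.27 at 6 h to -0.11 at 72 h.

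**Figure D2:**
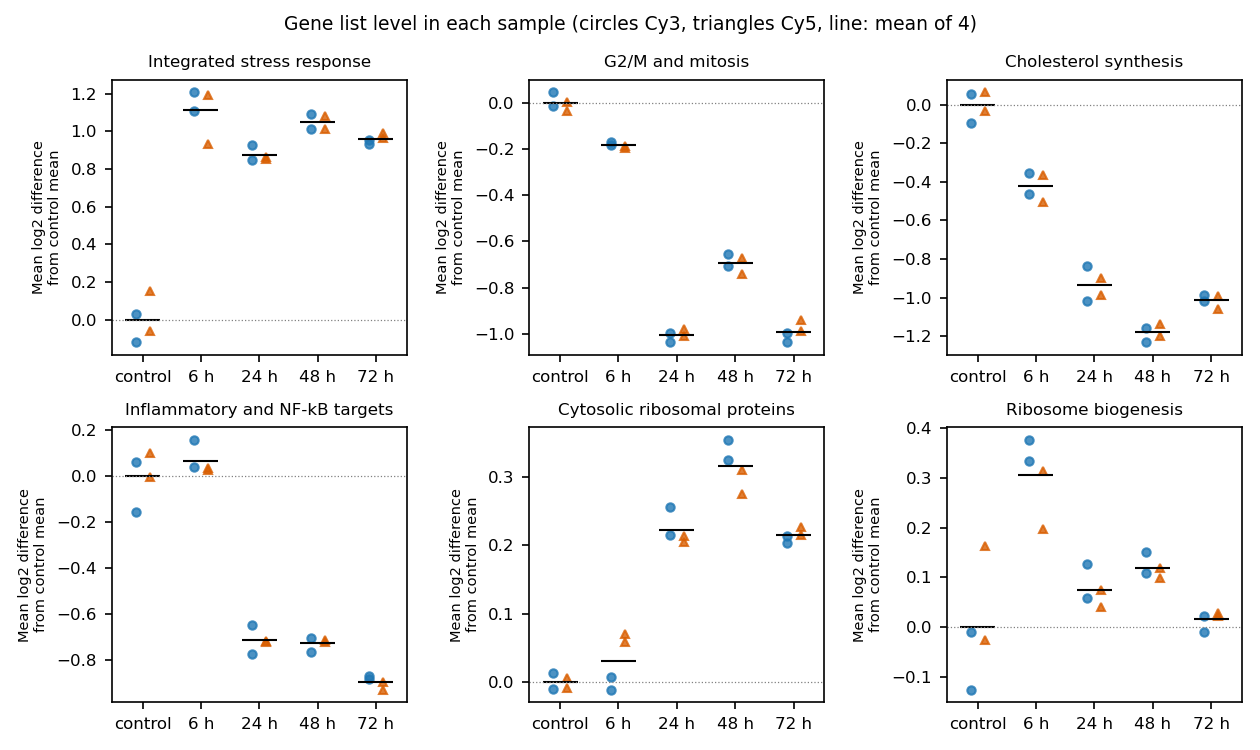
Mean log2 difference from the control mean over the genes of 6 fixed lists (y axis) in each of the 20 samples, by group (x axis); circles are Cy3 samples, triangles Cy5 samples and lines the mean of 4. The values have the fitted dye and slide terms removed. All samples with actinonin lie above all controls for the integrated stress response and below them for G2/M and cholesterol synthesis.

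**Figure D3:**
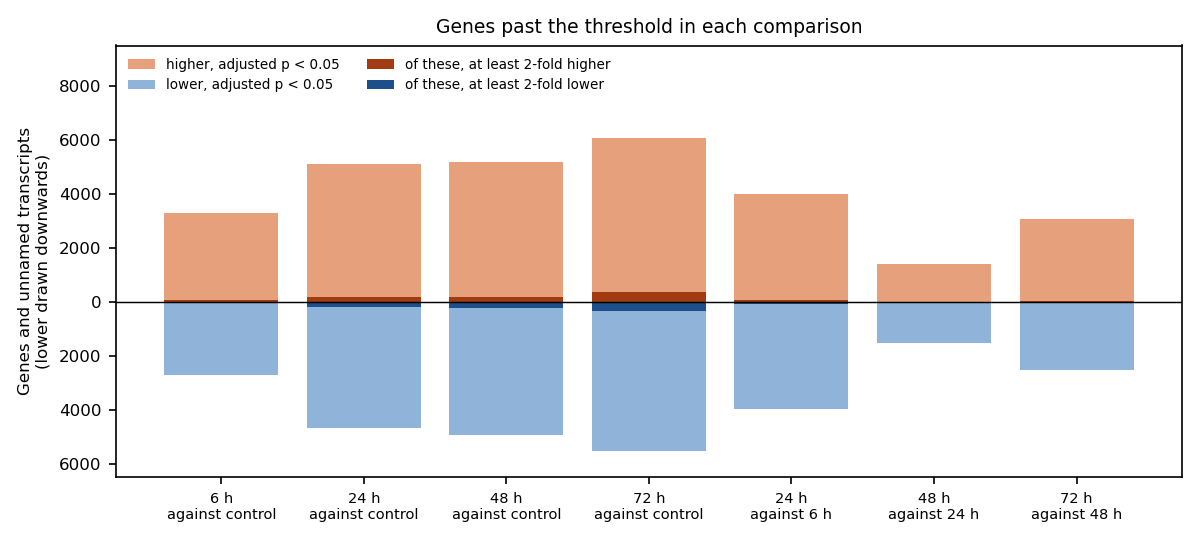
Numbers of genes and unnamed transcripts past the threshold in each of the 7 comparisons (x axis), with higher drawn up and lower drawn down (y axis) and darker bars for those changed by at least 2-fold. The count runs from 6002 at 6 h to 11605 at 72 h against the control.

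The step from 6 h to 24 h asks what changed after the early response. Car6 (3.46 ± 0.16), Cdsn (3.38 ± 0.11) and Tenm4 (2.74 ± 0.10) rose most and Cck (-3.02 ± 0.10), Ccl9 (-2.33 ± 0.10) and Ccl7 (-2.15 ± 0.11) fell most. G2/M genes fell in 30 of 30 (30 adjusted over the list alone; median -0.82; adjusted p = 0.00314 with an estimated correlation), and inflammatory genes in 16 of 19 with 0 up (17 and 0 adjusted over the list alone; adjusted p = 0.0164 with an estimated correlation). Ribosome biogenesis genes fell in 19 of 32 and rose in 1 (19 and 1 adjusted over the list alone; adjusted p = 0.497 with an estimated correlation), Nop58 at -0.50 ± 0.08, and integrated stress response genes fell in 18 of 36 and rose in 3 (21 and 3 adjusted over the list alone; adjusted p = 0.637 with an estimated correlation), Gdf15 at -0.91 ± 0.10. Cytosolic ribosomal protein genes rose in 55 of 78 and fell in 0 (61 and 0 adjusted over the list alone; adjusted p = 0.0702 with an estimated correlation). The count was 7977, 3987 up and 3990 down. It was 4457 without scaling between arrays and 8174 within slide 2.

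Between 24 h and 48 h fewer genes changed, 2940, with 1414 up and 1526 down and 3 up and 1 down by at least 2-fold. Crispld2 (1.22 ± 0.09), Tmem171 (1.19 ± 0.15) and the myosin phosphatase inhibitor gene Ppp1r14a (0.94 ± 0.07) rose most, and Il1rl1 (-0.93 ± 0.13), Prl2c5, which has close paralogs (-0.91 ± 0.10), and Bnc1 (-0.90 ± 0.08) fell most. Bnc1 was well above background in only 1 of 4 samples of 48 h, so the size of its fall is uncertain. G2/M genes rose in 25 of 30 and fell in 0 (28 and 0 adjusted over the list alone; median 0.32; adjusted p = 0.00841 with an estimated correlation), so that they lay below the control at both times by different amounts. Glycolysis and hypoxia-inducible genes rose in 12 of 27 and fell in 2 (19 and 2 adjusted over the list alone; adjusted p = 0.0140 with an estimated correlation), Bnip3 by 0.68 ± 0.07. NRF2 targets fell in 14 of 24 and rose in 1 (18 and 1 adjusted over the list alone; adjusted p = 0.0140 with an estimated correlation), Gsta4 at -0.68 ± 0.06. Of 5 epithelial markers 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.23, up to 0.95 over 7 other scalings; adjusted p = 0.0705 with an estimated correlation). Of 5 adipocyte markers 2 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.28, as close to 0 as -0.077 over the scalings; adjusted p = 0.0705 with an estimated correlation). Both were past the threshold with the preset correlation. Lysosome genes fell in 12 of 30 and rose in 0 (13 and 0 adjusted over the list alone; adjusted p = 0.102 with an estimated correlation). Samples of 24 h shared arrays only with samples of 72 h, and samples of 48 h only with those of 6 h or the control, so each step to or from 48 h compares different arrays. The same holds for the step from 6 h to 24 h and for 24 h and 72 h against the control. For the step from 24 h to 48 h the count was 344, with 27.9% of calls up in place of 48.1%, without scaling between arrays. It was 1883 with scaling to the 75th percentile, 1775 without the 24 h sample 2_Cy5 and 4048 within slide 2.

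Between 48 h and 72 h, 5607 genes changed, 3081 up and 2526 down. The Wnt pathway ligand gene Rspo3 (1.65 ± 0.14), the lysophospholipase gene Enpp2 (1.57 ± 0.12) and Tenm4 (1.54 ± 0.09) rose most. Cck (-1.64 ± 0.09), Tmem171 (-1.14 ± 0.15) and the troponin gene Tnnt2 (-1.10 ± 0.08) fell most. G2/M genes fell in 24 of 30 and rose in 0 (26 and 0 adjusted over the list alone; median -0.29; adjusted p = 0.0461 with an estimated correlation). Extracellular matrix genes rose in 17 of 30 and fell in 5 (19 and 5 adjusted over the list alone; adjusted p = 0.346 with an estimated correlation), Col1a1 by 0.67 ± 0.09, and lysosome genes rose in 16 of 30 and fell in 2 (19 and 2 adjusted over the list alone; adjusted p = 0.285 with an estimated correlation). Without scaling between arrays the count was 1810 with 69.6% up in place of 54.9%. With scaling to the 75th percentile 42.4% of calls were up. The count was 6842 within slide 2.

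Changes at different times were set against each other across 24205 genes with a value in every sample, which are not independent replicates. The Pearson correlation of log2 changes was 0.92 between 24 h and 72 h, 0.89 between 24 h and 48 h and 0.87 between 48 h and 72 h. With 6 h it was 0.54 for 24 h, 0.60 for 48 h and 0.48 for 72 h. All comparisons share the controls, and 20 simulations of unchanged groups against them gave 0.69, 0.54 and 0.54 for the later pairs and 0.41, 0.47 and 0.41 for the pairs with 6 h. With the controls split so that each time of a pair had its own, the observed values were 0.83, 0.78, 0.79, 0.40, 0.46 and 0.37 in the same order. The slide and dye terms were still fitted over all samples, so the changes were not fully separate. Unchanged groups simulated with split controls gave 0.21, 0.07, 0.07, -0.04, -0.04 and -0.04, and the highest of these is that of 24 h and 72 h, whose samples share arrays. The covariances were 0.122, 0.0948, 0.115, 0.0345, 0.0386 and 0.0379, against simulated covariances of 0.00633, 0.00447, 0.00448, 0.00319, 0.00321 and 0.00318. For 24 h and 72 h, 4431 genes rose at both and 3930 fell at both, where independent lists would share 1276 and 1067. Another 15 went in opposite directions. For 6 h and 72 h, 1887 rose and 1680 fell at both, with 822 and 621 for independent lists, and 658 went in opposite directions.

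Whether both slides gave the same 6 h change was tested by the interaction of slide and treatment, over the 8 samples of both groups. With limma, 0 of 24250 genes were past the adjusted threshold and 560 were at an unadjusted p under 0.05. Chance alone would give a share of 0.05 of the genes, which is more than these 560, so the test was conservative here. The 0 calls therefore do not show that both slides gave equal changes. On slide 1 each control shared its array with a 6 h sample, and on slide 2 none did. Slide and array pairing can thus not be told apart in this test. The 6 h changes of slide 1 and slide 2 correlated across genes at 0.77. Fgf21 was at 1.39 on slide 1 and 2.26 on slide 2, Trib3 at 2.09 and 2.80 and Gadd45a at 2.30 and 2.73. Without the control sample 2_Cy5 the test called 70 genes, and without the control sample 2_Cy3, 4.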

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

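In this part, the tests of array 10 and of array partners for the mitotic genes were chosen after the results were seen. Each step between successive times had genes past the threshold, and these steps also differ in array partners and in the time since treatment began. The step from 6 h to 24 h called 7977 genes and 13 lists, from 24 h to 48 h 2940 genes and 13 lists, and from 48 h to 72 h 5607 genes and 12 lists. With loess but no scaling between arrays the step to 48 h called 344.

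Mitotic genes were lower at 24 h and 72 h than at 48 h: Plk1 was at -1.36 ± 0.06, -0.99 ± 0.05 and -1.33 ± 0.06, and Kif23 at -1.21 ± 0.05, -0.75 ± 0.05 and -1.14 ± 0.05, at 24, 48 and 72 h. The median of the G2/M list at 48 h lay 0.355 above the mean of those at 24 h and 72 h. Without loess within arrays this gap was 0.359, and without array 10 it was 0.360, which argues against either as its source. No array (0 of 10) held a 48 h sample beside one of 24 h or 72 h, so an effect of the array partners cannot be told apart from time. A different share of dividing cells at 48 h, or a difference in the plates harvested, may also account for it and was not tested.

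Some samples stood apart from the other 3 of their group by a gap test that flags about 1 group in 20 by chance. It did so for 1 of 20 groups of array quality measures, 6 of 155 groups of list scores and 5 of 85 groups of gene values. List scores and gene values had the fitted dye and slide terms removed, and the quality measures were raw values. Median background was higher in every Cy5 sample than in every Cy3 sample, so the test could not flag a single sample by that measure. The rate of 1 in 20 therefore does not hold for the quality measures. The control 1_Cy5 had 105 outlying spots against 148 to 153 in the others. The mitochondrial ribosomal protein score of the control 2_Cy5 was -0.033 (others 0.0098 to 0.013). At 6 h, sample 1_Cy5 had a serine and one-carbon score of 0.169 (others 0.278 to 0.294) and a log2 intensity of 15.04 for Chac1 (others 15.31 to 15.34). Sample 2_Cy3 of that time had an inflammatory score of 0.160 (others 0.027 to 0.042). At 24 h, sample 1_Cy3 had an immediate early gene score of -0.106 (others -0.187 to -0.179), Lonp1 at 15.69 (others 15.81 to 15.82) and Mcm5 at 13.53 (others 13.41 to 13.42). At 48 h, Hspd1 was 16.14 in sample 2_Cy3 (others 16.21 to 16.22). At 72 h, sample 2_Cy3 had a complex I score of 0.038 (others 0.081 to 0.089) and a glycolysis and hypoxia score of 0.328 (others at most 0.304). Sample 2_Cy5 of that time had Ccnb1 at 12.82 (others 12.60 to 12.61).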

How the results depend on the processing

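Over 22 alternatives other than single samples left out, named genes kept direction and side of the threshold in 5184 of 5387 results. The call was lost in 187 and gained in 15, and 1 turned: Kdr at 24 h, 0.00056 without the slide term in place of -0.26. Lists did so in 4225 of 4588, with 224 calls lost and 139 gained. Leaving out single samples kept 2024 of 2040 gene results (13 lost, 3 gained) and 1677 of 1736 list results (38 lost, 21 gained). Genes named by the size of their change or by smallest adjusted p were picked from these same data. This favours unchanged calls in the gene results, so their share does not hold for all genes tested. Signal near background limits the dim genes, and changes of 0.25 on the log2 scale were recovered in at most 44% of simulated cases. The simulations changed far fewer genes than were called in the data, so this share need not hold for the data. Where no cause is named for a count that moved by over 1.5 times, the cause was not tested. The fits without array 10 and over named genes were chosen after seeing the data.

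Loess without scaling between arrays gave 6134 genes at 24 h, and 4457, 344 and 1810 for the steps to 24, 48 and 72 h. Scaling to the 75th percentile gave 1883 for the step to 48 h, and the fit without a dye term 1811. Without the slide term the steps to 48 h and 72 h gave 880 and 2739. With fewer samples, slide 1 alone gave 1.1e2 genes (rounded) at 6 h and the 2 groups alone 2782. A stricter adjusted p of 0.01 gave 3918 at 6 h and 1123 and 3213 for the steps to 48 h and 72 h. Requiring a 2-fold change as well gave 72, 361, 389 and 711 against the control and 164, 4 and 36 for the steps. List shifts against the control numbered 66, 12 with an estimated correlation and 102 with fry. The mean correlation between times, 0.716, was 0.603 with split controls, which still shared the slide and dye terms. The slide interaction, at 0 genes, gave 4 without array 10. Other alternatives kept every count within 1.5 times, among them the authors' series matrix with 6144, 9784, 10251 and 11567 genes at 6, 24, 48 and 72 h. Without array 10 these were 5446, 8804, 8336 and 10716, and 8209, 2252 and 4961 for the steps.

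With single samples left out the counts ranged from 4875 to 6294 at 6 h, 8085 to 9928 at 24 h, 8459 to 10466 at 48 h and 10171 to 11772 at 72 h. They ranged from 6467 to 8416 for the step to 24 h, 1775 to 2388 for that to 48 h (1775 without the 24 h sample 2_Cy5) and 4094 to 5314 for that to 72 h. The lists ranged from 61 to 71, the correlation from 0.703 to 0.735. The slide interaction ranged from 0 to 70 genes, with 70 without the control 2_Cy5 and 4 without the control 2_Cy3.

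The number and dye in the titles recur in every group. Deviations of samples with the same number and dye correlated at -0.084 on average over 40 pairs, and 1 pair was over 0.1. The 10 pairs on 1 array averaged 0.455 and were at 0.280 or more, above every pair of different groups on different arrays (at most 0.266). Each sample thus correlated best with its array partner, which carries the other dye and so another name. That 0 of 20 correlated best with their own name therefore tests nothing. The correlations of the 40 pairs give no sign that the names pair samples. With the name as a replicate block, 6250, 9395, 10179 and 11330 genes were called at 6, 24, 48 and 72 h, 7656, 2718 and 5446 in the steps and 63 lists.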

Other observations

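In this part, the tests of array 10 were chosen after the results were seen. Members of the lists of NRF2 targets, interferon-stimulated genes and glycolysis and hypoxia-inducible genes also changed, in both directions. None of these lists was past the threshold against the control with an estimated correlation. NRF2 targets rose in 12 of 24 and fell in 2 at 24 h (13 and 2 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation), Gsta4 by 1.68 ± 0.07 and the heme oxygenase gene Hmox1 by 1.34 ± 0.07, while the thioredoxin gene Txn1 was at -0.31 ± 0.05. At 6 h 7 rose and 6 fell, with 7 and 9 at 48 h and 9 and 9 at 72 h. Interferon-stimulated genes rose in 6, 11, 11 and 13 of 23 and fell in 2, 3, 3 and 3 at 6, 24, 48 and 72 h. At 72 h the count adjusted over the list alone was 13 and 3 (adjusted p = 0.420 with an estimated correlation), with Bst2 at 1.07 ± 0.08 and Psmb8 at 0.83 ± 0.09. Glycolysis and hypoxia-inducible genes fell in 15 of 27 and rose in 6 at 6 h (15 and 6 adjusted over the list alone; median -0.16; adjusted p = 0.25 with an estimated correlation). They rose in 13 and fell in 7 at 72 h (13 and 7 adjusted over the list alone; median 0.087, up to 0.151 over 7 other scalings; adjusted p = 0.310 with an estimated correlation). The preset call was lost under 2 of these at 6 h and 4 at 72 h. The oxidoreductase gene Ero1a was at 1.77 ± 0.09 and Ndrg1 at 1.89 ± 0.07 at 72 h. At 24 h 9 of the list rose and 11 fell, and at 48 h 14 and 9. Immediate early genes fell in 11, 10 and 12 of 20 at 24, 48 and 72 h (12 at 72 h adjusted over the list alone; adjusted p = 0.226 with an estimated correlation), Egr2 to -1.57 ± 0.10 at 72 h. They rose in 3, 4 and 2, with Klf4 at 0.92 ± 0.07 at 72 h, and at 6 h 5 rose and 4 fell. p53 targets went both ways, with 7, 8, 8 and 9 of 24 up and 5, 5, 10 and 10 down, and were not past the threshold by camera. Bbc3 was at 0.93 ± 0.06 and Perp at 1.00 ± 0.09 at 72 h, and Ckap2, a spindle protein gene, at -0.88 ± 0.05.

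Mitochondrial ribosomal protein and complex I genes went in both directions. Mitochondrial ribosomal protein genes rose in 25, 21, 30 and 15 of 78 and fell in 10, 14, 20 and 24 at 6, 24, 48 and 72 h (adjusted p = 0.504 at 6 h with an estimated correlation), with Mrpl23 at 0.76 ± 0.06 and Mrps6 at -1.01 ± 0.06 at 72 h. Complex I genes rose in 0, 5, 5 and 9 of 36 and fell in 7, 1, 4 and 3 (adjusted p = 0.504 at 6 h with an estimated correlation), with Ndufa6 at 0.72 ± 0.06 and Ndufb7 at -0.22 ± 0.05 at 72 h. Of 4 measured genes of reported actinonin targets 2 rose at 6 h, Pdf and the aminopeptidase gene Lap3 (0.26 ± 0.05). Of these genes 1 rose at 24 h and 1 fell at 48 h and at 72 h. Markers of other cell types were few among the genes measured. Skeletal muscle markers fell in 3 of 5 at 24 h (adjusted p = 0.166 with an estimated correlation), Tnnt2 to -1.40 ± 0.09 and Acta1 to -0.38 ± 0.07. Their median was -0.34 at 24 h, -0.00045 at 48 h and -0.14 at 72 h. On average they were at -0.42, -0.34 and -0.55 at these times. Cartilage and bone markers fell in 5, 6 and 5 of 9 at 24, 48 and 72 h and rose in 1, 0 and 1 (adjusted p = 0.121 at 72 h with an estimated correlation), the osteopontin gene Spp1 to -1.36 ± 0.10. The macrophage and leukocyte markers had a median of -0.14 and were at -0.30 on average at 72 h, with Cd14 at -1.35 ± 0.08. At 72 h, 2 of 5 endothelial markers rose and 1 fell, 1 of 5 epithelial markers rose and 1 fell. At that time 1 of 5 adipocyte markers rose and 3 fell (the transcript of Lpl at 0.91 ± 0.09) and 1 of 7 neural markers rose and 2 fell. None of these 4 lists was past the threshold against the control by camera. The median and mean of a list differed in sign for some lists with members in both directions, such as p53 targets at 6 h and glycolysis genes at 24 h.

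Cytosolic ribosomal protein genes rose from 24 h, and 2 technical explanations were tested. At 48 h, 203 other named genes matched on intensity had a median of -0.13, where the ribosomal protein genes had 0.33, a ratio of -0.380. The ribosomal protein genes thus rose relative to genes of like intensity. Loess and quantile scaling largely remove a shift common to bright genes beforehand, so the ratio cannot decide whether normalization shifted all bright genes. The match was imperfect, with mean log2 intensities of 16.3 and 16.9. Over the scaling alternatives the lowest list median at 48 h was 0.212, which argues against the choice of scaling. A rise of these transcripts with actinonin or with time in culture may be considered, and the design cannot separate these.

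Array 10, with a control and a 48 h sample, had the highest shares of spots well above background. Its dimmer channel exceeded the highest value elsewhere by 7.79 percentage points, which restates what was seen and tests no cause, so a property of the whole array stays open. Without it 8336 genes were called at 48 h, which argues against array 10 as the source of most of the 10139 calls. No biological explanation was tested.

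Other splits of the 8 samples of each comparison into 2 groups of 4 were fitted with the array correlation held and with dye and slide as terms, 35 splits each with the real one. A term equal to the split was left out. At 24 h the real split called 8267 genes and the highest other 21, at 48 h 7133 and 70, and at 72 h 10086 and 20. For the steps to 24, 48 and 72 h the real splits called 6519, 2770 and 5751 and the highest others, which separated the dyes, 148, 428 and 288. In each of these 1 of 35 splits, the real one, was as large, which is the lowest share this test can give. At 6 h the real split called 3140 genes, and 2 of 35 splits gave as many, the other being the split by slide with 4328, which had no slide term. So this count alone does not exclude chance. The split by dye, with no dye term, called 228, and the other splits, with both terms, called 0. Within slide 1 and slide 2 the 6 h comparison called 1.1e2 (rounded) and 4697 genes, and 6002 with slide as a term. These fits held different numbers of samples, so the counts do not compare the slides.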
